A study of Mus musculus with 16 samples.

How the data were processed

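Gene expression was measured by RNA sequencing of colon tissue in 16 libraries that fall into 4 groups of 4, made by crossing genotype (F/F or DIEC) with drink (water, called naive here, or 2.5% dextran sulfate sodium, DSS, sampled on day 3). Per the labels, the RNA of 3 mice was combined in each library, so every group stands for 12 mice, and the spread between libraries is the spread between pools. The mice were C57BL/6 animals of 8 weeks. RNA was extracted with Trizol from frozen tissue and made into libraries with the Illumina TruSeq RNA kit, per the labels' protocols. That kit does not mark strand in its standard form, whereas the file header gives a strand option to the counting step. Genes that overlap on opposite strands are therefore taken as uncertain here.

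Per the submitters' processing notes, reads were handled with bcl2fastq, aligned with STAR 2.2.0c and counted with HOMER 4.9. Per the file headers, HOMER counted raw reads over all exons of its mm9 gene models, condensed to a single model per gene, and then compared the 4 groups pairwise. The processing notes name mm10 as the genome. The start and end positions in the table are those of mm9: of 21660 genes that could be matched to the mm10 annotation GENCODE M21, 1218 (5.6%) lay inside their mm10 gene with a margin of 1000 bp. Positions are printed as the table gives them, as mm9, and the build of the alignment itself stays unsettled.

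The deposited signal values are reads per gene that the authors divided by a single factor per library, so that every library sums to between 26554078 and 26554094. In each library the values were whole multiples of the value of 1 read, which ran from 0.765 to 1.331. In every library 100% of the values above 0 lay within 0.01 of such a multiple, which is the rounding of the file, and so the reads behind each value were recovered. In the library F/F DSS 1 a read was worth 1.007, so near to 1 that recovery there rests on the high values. The authors' deposited log2 fold changes compare the second group named with the first. The deposited p-values, raw and adjusted, belong to the same comparisons, and the statistical tool behind them is not given in the sources used here. Of the gene symbols in the name column, 27 had been turned into dates by a spreadsheet and were read from the annotation column.

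The recovered reads on genes numbered 19957413 to 34733832 per library, and the library totals in the headers 25631586 to 42746008, of which 77.0 to 81.7% were on genes. At this depth a gene with 0 reads in a group of 4 libraries is given a floor of 3 reads over the group. Such floors, and the intervals of ratios with few reads (exact, 95%), cover counting error only, since reads without molecular identifiers are not independent molecules.

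The plan foresaw a count test, and, should the values turn out to be normalized, limma. As the deposited unit is scaled, the main test was limma 3.58.1 in R 4.3.3, with eBayes using trend and robust settings, on log2(value + 1). Genes with a value of at least 1 in at least 4 libraries were kept, 18267 of 24421. All 16 libraries entered a single model with a mean per group, and a gene was called where its Benjamini-Hochberg adjusted p was under 0.05. A log2 change on this scale understates the change of low genes. Every "adjusted p" for a gene comes from this limma model unless another tool is named. Group values are means ± SD over the 4 libraries on the deposited scale. Count tests on the recovered reads (edgeR 4.0.16 quasi-likelihood, DESeq2 1.42.0, limma voom) were run on the 15695 genes that edgeR's expression filter kept.

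Fixed before the data were examined were 33 lists of genes for pathways and for cell types that colon tissue can hold, of which 32 had at least 4 measured members. They were tested with limma's camera at its preset correlation of 0.01, two-sided and adjusted over the 160 tests of 32 lists in 5 comparisons. Camera asks whether a list moves against the other genes, so its direction can differ from the sign of the list's median. Of the 160 tests 84 gave a call, and 5 of these also passed with an estimated correlation: fatty acid oxidation and LXR targets with the deletion in naive and in DSS colon, and antimicrobial defence in the interaction. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone. The list of sex-linked genes served as a check of the pools.

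Genes to be named were fixed by rule before the data were examined: Ncor1, then the 5 largest rises and falls per comparison among called genes, and then up to 4 members with the smallest adjusted p of each list that was called or had 2 members called. The second part asked for non-overlapping groups in the 4 comparisons of 2 groups, but not in the interaction. Predicted genes, small RNAs and antigen receptor segments were passed over in the second part. From the genes this rule gives, the text names 43, 40, 33, 42 and 18 in the 5 comparisons, chosen for length after the values were seen, and some genes are not reported here. Members of near-identical gene families (Sprr2a1, Clca4b, Ly6c2, Ly6g, Saa1, H2-D1, H2-T3, Itln1, Ang4 and Mptx1 among those named) can share reads with their copies, and their values are uncertain to that extent. The list members Fer1l6 and Sh2d6 were not analysed here, and Elane, Ngp, Fgf15, Nr0b2 and Hmgcs1 were too low to be tested.

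Alternatives chosen before the data were examined covered the filter on low values, the pseudocount (0.1 and 5), quantile normalization, limma without trend, a fold of at least 1.5, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a rescaling by edgeR's TMM factors, the count tests above, and a run without DIEC naive 1 and DIEC DSS 3, which stood apart. Library totals alone are what the deposited scaling already is, so that alternative is the main setting. All libraries of the table were used.

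The tests were tried on simulated reads drawn from the means of F/F naive, used for all groups, and the real library sizes. For the deletion in naive colon (18050 genes), limma found 26, 42, 47 and 48 of 50 genes changed by 1.5, 2, 3 and 4 fold, and 11 of its 174 calls were of unchanged genes. For the interaction (18055 genes) it found 9, 38, 40 and 46 of 50, with 6 unchanged genes among 139 calls. Camera called the planted list of 20 genes changed 2 fold in both simulations, and 2 and 0 of 100 lists of unchanged genes at an unadjusted p under 0.05. The simulated reads were drawn independently for each gene, so this trial does not test camera on lists of correlated genes. The changed genes rose and fell in equal numbers, so the trial holds no shift in scale between groups. Its counts of wrong calls therefore do not describe comparisons whose calls depend on the scaling. DESeq2 called 30 unchanged genes among 197 and 29 among 172 in the same simulations.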

Results

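RNA was sequenced from the colon of C57BL/6 mice in 16 libraries, each holding the combined RNA of 3 mice. The mice were either F/F, whose genotype label is wild type, or DIEC, in which NCoR1 is deleted in intestinal epithelial cells. NCoR1 is a corepressor that joins nuclear receptors to histone deacetylase 3. Mice of each genotype drank water (naive) or 2.5% DSS, a sulfated polysaccharide that injures the colon lining, and were sampled on day 3, which gave 4 groups of 4 libraries. The recovered reads on genes numbered 22502529 to 27547730 per library in F/F naive, 26363572 to 34733832 in F/F DSS, 19957413 to 29183138 in DIEC naive and 22883415 to 30342046 in DIEC DSS. The comparisons ask what DSS changes in each genotype, what the deletion changes without and with DSS, and where the response to DSS differs between genotypes. On the first principal component, which held 62.2% of the variance, all naive libraries lay between -45.4 and -28.3 and all DSS libraries between 14.9 and 55.6. On the second, with 12.7%, the library DIEC DSS 3 stood apart from the others of its group, at -44.7.

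The targeted gene was measured in every library first. Ncor1 (NM_011308, mm9 chromosome 11, 62129928 to 62252017, minus strand) was at 3445.2, 3730.4, 3585 and 3680.1 in the F/F naive libraries and at 4078.3, 3709.4, 3689.2 and 3736.5 in the F/F DSS libraries. It was at 1822.9, 1756.1, 1978.5 and 1805.2 in DIEC naive and at 1663.3, 1545.5, 1342.6 and 1602.5 in DIEC DSS, so that every DIEC library lay below every F/F library. The tissue also holds cells outside the epithelium, and reads were counted over all exons, so the remaining reads do not measure how complete the deletion was. Ncor1 did not change with DSS in F/F colon (log2 change 0.07 ± 0.07 SE, adjusted p = 0.42), although it passed after TMM rescaling (0.18, adjusted p = 0.032). In DIEC colon it fell by 0.26 ± 0.07 (adjusted p = 0.0042) on the deposited scale, while its change after TMM rescaling was -0.01 (adjusted p = 0.93). Xist was between 14627.4 and 33529.6 in all libraries, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in all 16.

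In F/F colon, 3 days of DSS lowered all 21 proliferation genes and 11 of 16 monocyte and macrophage markers. It raised 10 of 11 smooth muscle markers, 6 of 18 interferon genes and 10 of 17 clock genes. Camera called these lists at its preset correlation and none of them with an estimated one (adjusted p = 0.38, 0.55, 0.38, 0.55 and 0.28 with an estimated correlation). Lgr5, the receptor that marks crypt stem cells (mm9 chromosome 10, 114887370 to 115024836), fell from 282 ± 49.6 to 37.3 ± 38.7 (SD, n = 4; log2 change -3.5 ± 0.65 SE, adjusted p = 0.00066). Pcna, the sliding clamp of DNA replication (mm9 chromosome 2, 132075022 to 132078916), fell from 1610 ± 156 to 634 ± 116 (log2 change -1.36 ± 0.11, adjusted p = 2.6e-07). Myh11, the smooth muscle myosin, rose from 36100 ± 6580 to 63200 ± 5040 (0.82 ± 0.13, adjusted p = 4e-05). Cxcl10, a chemokine induced by interferon, rose from 115 ± 19.4 to 730 ± 524 (2.45 ± 0.43, adjusted p = 0.00044).

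All 21 proliferation genes fell, 21 adjusted over the list alone and 21 after TMM rescaling, with a median log2 change of -1.87 (camera adjusted p = 3.7e-09; adjusted p = 0.38 with an estimated correlation). Among them Tyms, which makes thymidylate, fell by 1.18 ± 0.13 and Mcm7, part of the replicative helicase, by 1.58 ± 0.2. Of 18 crypt stem and Wnt target genes 11 fell and 1, Rnf43, rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.56 with an estimated correlation). Slc12a2, the sodium, potassium and chloride cotransporter of crypt cells, fell from 11000 ± 812 to 4310 ± 848. Neurog3, the transcription factor of endocrine progenitors, fell from 30.7 ± 2.93 to 6.02 ± 3.85, whereas the products of mature endocrine cells Chga (0.77 ± 0.08) and Pyy (0.7 ± 0.1) rose. Of the 15 enteroendocrine markers those 2 rose and 4 fell (Neurog3, Gcg, Nts and Sct), 2 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.9).

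Of 18 absorptive colonocyte markers 6 rose and 4 fell (7 and 4 adjusted over the list alone), or 9 and 1 after TMM rescaling, without a call for the list (camera adjusted p = 0.057). Cdhr5, a cadherin of the brush border, rose from 16200 ± 1600 to 30100 ± 2050 (adjusted p = 9.9e-07) and Hsd11b2, which inactivates glucocorticoids, from 7510 ± 665 to 13900 ± 1090. Guca2a, the precursor of guanylin, fell by 0.79 ± 0.21 (adjusted p = 0.0065). Of 16 goblet cell markers 8 fell and 1, Creb3l1, rose, 9 and 2 adjusted over the list alone (camera adjusted p = 0.069). Agr2, a disulfide isomerase needed for mucin folding, fell from 64300 ± 7010 to 29600 ± 4180. Of 18 genes of the unfolded protein response 10 fell and 1, Atf3, rose, likewise adjusted over the list alone (camera adjusted p = 0.049; adjusted p = 0.76 with an estimated correlation). The chaperone Hsp90b1 fell from 32900 ± 7080 to 14800 ± 2580. Among 21 junction genes 9 rose and 3 fell (Cldn2, Cldn15 and Dsc2), 10 and 3 adjusted over the list alone and 12 and 3 after TMM rescaling (camera adjusted p = 0.0079; adjusted p = 0.52 with an estimated correlation), and Cldn3, a sealing claudin, rose by 0.76 ± 0.11. Of 16 bile acid and xenobiotic receptor targets 4 rose (Abcc2, Abcc3, Abcb1a and Nr1i2) and 2 fell (Slc51a and Slc51b), also over the list alone (camera adjusted p = 0.17). The bile acid exporter subunit Slc51a fell from 23.4 ± 13.8 to 1.58 ± 0.505. Of 23 genes of fatty acid oxidation and PPAR targets 5 rose and 7 fell, also over the list alone (camera adjusted p = 0.97), and the fatty acid binding protein Fabp2 fell by 2.4 ± 0.36.

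Of 16 monocyte and macrophage markers 11 fell and none rose, 13 adjusted over the list alone (camera adjusted p = 0.0047; adjusted p = 0.55 with an estimated correlation). The mannose receptor Mrc1 fell from 1500 ± 243 to 665 ± 44.3, the F4/80 antigen Adgre1 from 729 ± 151 to 269 ± 35.5 and the monocyte antigen Ly6c2 from 609 ± 179 to 98.4 ± 19.9. Of 14 B and plasma cell markers 3 fell, 3 adjusted over the list alone: Tnfrsf17, Mzb1 and Jchain, the joining chain of secreted immunoglobulin, which went from 35800 ± 6280 to 6440 ± 697 (camera adjusted p = 0.64). Of 15 T and NK cell markers 2 fell, also over the list alone (camera adjusted p = 0.47). Of 14 neutrophil markers 2 rose (Ly6g and Ltf) and 3 fell (Retnlg, Mpo and Fpr1), also over the list alone (camera adjusted p = 0.97). Ltf, the iron-binding lactoferrin, rose from 9.07 ± 2.73 to 34.9 ± 8.07, while Retnlg had 0 reads with DSS and was at least 32-fold lower against a floor of 3 reads over the group. Of 28 cytokines and chemokines 2 rose (Cxcl10 and Il6) and 1 fell, Il33, an alarmin, by 0.81 ± 0.2, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.33).

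Of 18 genes of the type I interferon response 6 rose, 5 adjusted over the list alone (camera adjusted p = 8.2e-05; adjusted p = 0.55 with an estimated correlation). Irf7, the regulator of interferon genes, rose by 1.34 ± 0.42 (adjusted p = 0.021), the antiviral radical SAM enzyme Rsad2 by 1.48 ± 0.48 (adjusted p = 0.025) and Ifit3 by 1.26 ± 0.36 (adjusted p = 0.012). The library F/F DSS 2 stood far above the other 3 of its group in each, for example at 12800 against 5610 to 6030 for Irf7. Without F/F naive 1, F/F naive 4 or F/F DSS 2, the calls of Irf7 (adjusted p of 0.055 to 0.065) and Rsad2 (0.059 to 0.071) ended. Tap2, a subunit of the peptide transporter of antigen presentation, rose by 1.11 ± 0.22, and with it Tap1 and H2-D1, 3 of 19 genes of that list (2 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.76 with an estimated correlation). After TMM rescaling 5 of the 19 rose, and camera on voom values did not call the list (adjusted p = 0.057). Of 18 antimicrobial and epithelial defence genes 4 fell (Ang4, Itln1, Lcn2 and Sprr2a1) and 1, Nos2, rose, 3 and 1 adjusted over the list alone (camera adjusted p = 0.83). The ribonuclease Ang4 went from 35600 ± 21900 to 1670 ± 1440 and the lectin Itln1 from 1400 ± 970 to 54.9 ± 28.9. Nos2, the inducible nitric oxide synthase, rose by 1.54 ± 0.49 (adjusted p = 0.022), a call that ended without F/F naive 1, F/F naive 4 or F/F DSS 4 (0.05 to 0.064).

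Of 17 clock genes 10 rose and 1, Clock, fell, also over the list alone (camera adjusted p = 0.00038; adjusted p = 0.28 with an estimated correlation). Per1 and Cry2, repressors of the clock's feedback loop, rose by 1.3 ± 0.16 and 1.4 ± 0.14, and Clock, an activator, fell by 0.74 ± 0.08. Of 11 smooth muscle markers 10 rose, 10 adjusted over the list alone (camera adjusted p = 1.2e-05; adjusted p = 0.38 with an estimated correlation), among them Smtn by 0.79 ± 0.11. Enteric neuron and glia markers rose in 5 of 13 (6 adjusted over the list alone; camera adjusted p = 0.0078; adjusted p = 0.55 with an estimated correlation) and posterior Hox genes in 5 of 8 (5; 0.01; adjusted p = 0.41 with an estimated correlation). The largest rises named by the rule included Higd1c (2.33 ± 0.39) and Nccrp1 (2.04 ± 0.3).

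All 8 adipocyte markers fell, 8 adjusted over the list alone (camera adjusted p = 0.0047; adjusted p = 0.55 with an estimated correlation), and the fat hormone Adipoq went from 305 ± 129 to 33.5 ± 37.9. Their mean log2 level, relative to all 16 libraries, was 1.59, 0.22, 1.4 and 1.08 in F/F naive 1 to 4. In F/F DSS 1 to 4 it was -0.41, -0.87, -2.91 and -2.83. Whether the amount of attached fat tissue differed between libraries was not tested. All 9 pancreatic acinar markers fell, 9 adjusted over the list alone (camera adjusted p = 0.00044; adjusted p = 0.53 with an estimated correlation). With voom on the recovered reads Pnlip (adjusted p = 0.28), Cpa1 (0.26) and Cela2a (0.35) were not called, nor was the list (camera adjusted p = 0.2). Pancreatic lipase, Pnlip, was at 5890 ± 7330 in naive libraries and had 0 reads with DSS, at least 8772-fold lower, and carboxypeptidase Cpa1, at 3700 ± 4300, was at least 5486-fold lower. Most of these reads came from F/F naive 4, without which the bounds were 3381-fold and 2429-fold. The F/F naive libraries 1 to 4 held 7931, 125, 32866 and 89610 reads of the 8 genes other than Clps. Cela2a had 25604 reads in the naive group and 3 with DSS, a ratio of 10200 (exact 95% interval 3500 to 49500). The share of reads on these 9 genes ran from 0.00595% in F/F naive 2 to 1.94% in DIEC naive 1 and was at most 0.00158% in every DSS library of either genotype.

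**Figure D1:**
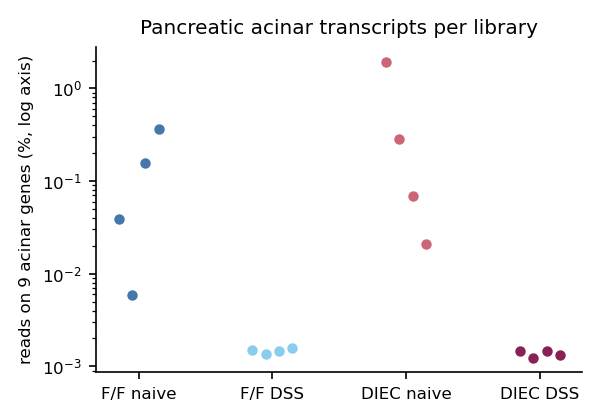
Percent of reads on 9 pancreatic acinar genes in each library, on a log axis, with 1 point per library and 4 libraries per group. The naive libraries spread from 0.00595% to 1.94%, and the DSS libraries lie at or below 0.00158%.

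In all, 8187 of 18267 genes changed with DSS in F/F colon, 2982 higher and 5205 lower. TMM rescaling shifted the log2 changes by a median over genes of 0.102 and gave 4173 higher and 4115 lower, with 7097 genes called under both scalings. The authors' deposited table has 3713 genes higher and 3666 lower at an adjusted p under 0.05. Of these, 6509 were called in the same direction here and 0 in the opposite direction. With a fold of at least 1.5 as well, 3447 genes passed.

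In DIEC colon, DSS lowered all 21 proliferation genes and 16 of 18 crypt stem and Wnt target genes. It raised 10 of 28 cytokines and chemokines and 9 of 18 antimicrobial and epithelial defence genes. Camera called these lists at its preset correlation and none of them with an estimated one (adjusted p = 0.41, 0.53, 0.24 and 0.24 with an estimated correlation). Cxcl5, a chemokine that draws neutrophils, rose from 39.1 ± 27.7 to 310 ± 60.5 (SD, n = 4; log2 change 3.17 ± 0.35 SE, adjusted p = 1.4e-06), and Cxcl1 (mm9 chromosome 5, 91320271 to 91322141), of the same kind, from 12.8 ± 0.722 to 58.3 ± 13.2 (2.08 ± 0.26, adjusted p = 1.6e-06). Tnf, a central inflammatory cytokine (mm9 chromosome 17, 35336312 to 35338952, minus strand), rose from 54 ± 8.41 to 190 ± 81 (1.72 ± 0.21, adjusted p = 1.4e-06). Nos2 rose from 58.4 ± 24.8 to 1040 ± 895 (3.88 ± 0.49, adjusted p = 1.8e-05). Ascl2, the transcription factor of crypt stem cells, fell from 117 ± 31.4 to 3.35 ± 1.82 (-4.83 ± 0.57, adjusted p = 4.3e-06).

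Of 28 cytokines and chemokines 10 rose and none fell, 8 adjusted over the list alone and 14 after TMM rescaling (camera adjusted p = 5.8e-07; adjusted p = 0.24 with an estimated correlation), Cxcl2 among them by 3.45 ± 0.65. Of 18 antimicrobial and epithelial defence genes 9 rose, 10 adjusted over the list alone, and 1, Ang4, fell by 3.54 ± 0.76 (camera adjusted p = 0.00053; adjusted p = 0.24 with an estimated correlation). The peptidoglycan-binding protein Pglyrp1 rose by 0.5 ± 0.09. Of 14 neutrophil markers 4 rose and 2 fell, also over the list alone (camera adjusted p = 0.024; adjusted p = 0.53 with an estimated correlation), and the list was not called with voom (0.76). Those that rose were Ltf (2.59 ± 0.35), Ly6g (1.44 ± 0.21), S100a8 (2 ± 0.45) and S100a9. S100a8, a subunit of the calprotectin of neutrophils, reached 17 ± 9.24. Those that fell were Retnlg and Mpo. Of 19 antigen presentation genes 6 rose, also over the list alone, and 10 after TMM rescaling (camera adjusted p = 5.7e-05; adjusted p = 0.55 with an estimated correlation), and the class I molecule H2-D1 rose by 0.96 ± 0.14. Of 18 type I interferon genes 4 rose, 1 adjusted over the list alone and 9 after TMM rescaling (camera adjusted p = 5.8e-05; adjusted p = 0.55 with an estimated correlation). The library DIEC DSS 2 stood above the other 3 of its group in these lists. The mean log2 level of the interferon genes, relative to their mean over all 16 libraries, was -0.14, 1.24, -0.6 and -0.09 in DIEC DSS 1, 2, 3 and 4, and that of the cytokines 0.35, 1.18, -0.25 and 0.63. The T and NK cell markers were at -0.71, 0.9, -1.3 and -0.16, and the B and plasma cell markers at -1.01, 1.17, -4.01 and 0.17. The list of macrophage markers was not called (camera adjusted p = 0.12), and of its members Mrc1 fell by 1.07 ± 0.14 and Ly6c2 by 2.43 ± 0.3. Jchain fell from 22500 ± 5190 to 4960 ± 1600.

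All 21 proliferation genes fell, 21 adjusted over the list alone and 21 after TMM rescaling, with a median log2 change of -2.79 (camera adjusted p = 2.4e-08; adjusted p = 0.41 with an estimated correlation), including Tyms (-1.66 ± 0.13) and the helicase subunit Mcm6 (-3.03 ± 0.3). Of 18 crypt stem and Wnt target genes 16 fell, 16 adjusted over the list alone, while 11 fell and 2 rose after TMM rescaling (camera adjusted p = 0.0027; adjusted p = 0.53 with an estimated correlation). Axin2, a feedback target of Wnt signalling, fell from 491 ± 59.1 to 75 ± 19.2 and Slc12a2 from 13200 ± 1120 to 4180 ± 668. Neurog3 fell from 168 reads to 3 in the group, a ratio of 60.4 (exact 95% interval 20.3 to 296), while Pyy rose by 1.2 ± 0.1. The 15 enteroendocrine markers, of which 3 rose and 2 fell, also over the list alone, or 7 and 1 after TMM rescaling, had a median of 0.16 and a mean of -0.2 (camera adjusted p = 0.026, upward; adjusted p = 0.51 with an estimated correlation).

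Of 18 absorptive colonocyte markers 7 rose and 3 fell, also over the list alone, or 10 and 2 after TMM rescaling (camera adjusted p = 0.0033; adjusted p = 0.35 with an estimated correlation). Cdhr5 rose from 16800 ± 1430 to 33700 ± 3310, Ceacam20, an adhesion molecule of the brush border, by 0.66 ± 0.11, and Lypd8, a secreted flagella-binding protein and the most abundant transcript in every DIEC library, by 0.63 ± 0.13. Of 16 goblet cell markers 3 rose and 7 fell, also over the list alone (camera adjusted p = 0.58), with Agr2 down by 0.97 ± 0.14 and Fcgbp, a mucus protein, up by 0.96 ± 0.22. After TMM rescaling 5 rose and 2 fell. Of 21 junction genes 11 rose and 3 fell, also over the list alone, or 14 and 3 after TMM rescaling (camera adjusted p = 0.00028, upward, with a median of 0.29 and a mean of -0.03; adjusted p = 0.35 with an estimated correlation). Those that fell, the pore-forming claudins Cldn2 (5240 ± 196 to 367 ± 78.1) and Cldn15 (2310 ± 418 to 414 ± 43.9) and Dsc2, fell in both genotypes. Of 23 genes of fatty acid oxidation 6 rose and 10 fell, also over the list alone, and 7 rose and 6 fell after TMM rescaling (camera adjusted p = 0.7). Fabp2 fell by 3.55 ± 0.36, and Acadl, a dehydrogenase of long-chain fatty acids, rose by 0.67 ± 0.09. Of 17 clock genes 10 rose and 2 fell, also over the list alone, or 12 and 1 after TMM rescaling (camera adjusted p = 0.00017; adjusted p = 0.25 with an estimated correlation), with Per1 up by 0.98 ± 0.16 and Clock down by 0.93 ± 0.08. All 11 smooth muscle markers rose, also over the list alone (camera adjusted p = 7.1e-09; adjusted p = 0.24 with an estimated correlation), among them Actg2 (1.07 ± 0.12) and Des (1.1 ± 0.14). Neuron and glia markers rose in 8 of 13, 8 adjusted over the list alone (camera adjusted p = 6.3e-06; adjusted p = 0.3 with an estimated correlation).

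The largest rises named by the rule were led by Clca4b, a calcium-activated chloride channel regulator, from 498 ± 206 to 9220 ± 3930 (4.2 ± 0.59), with Tex19.1 (3.19 ± 0.69) and the serine protease Prss22, which went from 3 to 70 reads in the group, a ratio of 21.7 (exact 95% interval 7.11 to 108). All 9 acinar markers fell, also over the list alone (camera adjusted p = 0.0019; adjusted p = 0.55 with an estimated correlation). With voom Pnlip (adjusted p = 0.18), Cela2a (0.25) and the list (0.15) were not called. Pnlip, at 22300 ± 34300 in naive libraries, had 0 reads with DSS, at least 28806-fold lower (7667-fold without DIEC naive 1, which held most of these reads), and Cela2a went from 28900 ± 45500 to 1.18 ± 1.09. Of 8 adipocyte markers 6 fell, 7 adjusted over the list alone (camera adjusted p = 0.17). Their mean log2 level, relative to all 16 libraries, was 0.64, -1.44, 0.3 and -2.29 in DIEC DSS 1 to 4. In all 9552 genes changed, 2250 higher and 7302 lower. TMM rescaling shifted the log2 changes by a median over genes of 0.253 and gave 4579 higher and 4813 lower, with 7063 genes called under both scalings. The authors' deposited table has 3653 higher and 3730 lower, 5936 of them called in the same direction here and 0 in the opposite. With a fold of at least 1.5, 5353 passed.

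The responses to DSS in F/F and in DIEC colon, which share no libraries, were compared across genes, which are not independent replicates. Log2 changes correlated at a Pearson r of 0.81 and a Spearman rho of 0.76 over 18267 genes. Higher in both were 1659 genes, where independent lists would share 367.3, and lower in both 4750, where they would share 2080.6, while 44 genes moved in opposite directions.

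**Figure D2:**
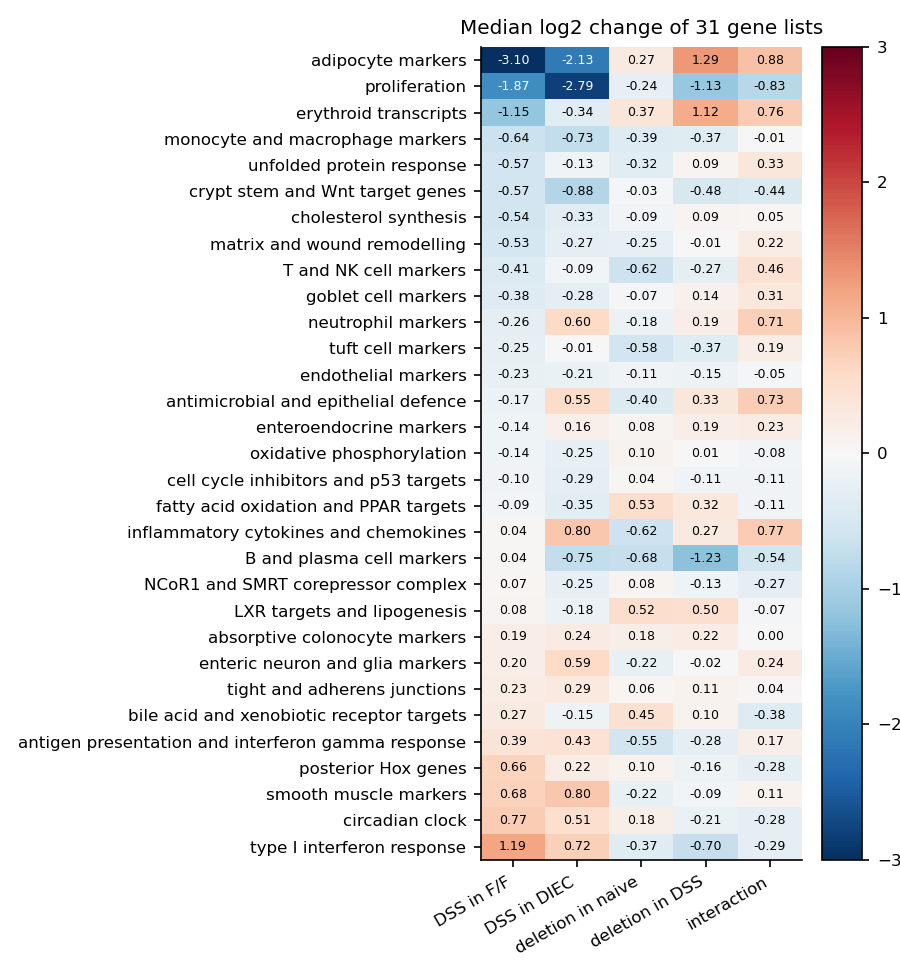
Median log2 change on the deposited scale of the measured members of 31 gene lists (a line each, pancreatic acinar markers left out) in the 5 comparisons (columns), with colour from blue (lower) to red (higher) and the value in each cell. Proliferation is at -1.87 and -2.79 with DSS, and fatty acid oxidation at 0.53 and 0.32 and LXR targets at 0.52 and 0.5 with the deletion.

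In naive colon, the deletion raised 13 of 23 genes of fatty acid oxidation and PPAR targets. It raised 6 and lowered 1 of 16 LXR targets and lipogenesis genes. Camera called both lists, also with an estimated correlation (adjusted p = 0.0097 and 0.014 with an estimated correlation). Abcg1, a cholesterol exporter and target of the oxysterol receptor LXR (mm9 chromosome 17, 31194639 to 31254926), rose from 218 ± 13.8 in F/F to 899 ± 53.7 in DIEC (SD, n = 4; log2 change 2.04 ± 0.11 SE, adjusted p = 1.7e-09). Arg2, the mitochondrial arginase (mm9 chromosome 12, 80231775 to 80257288), rose from 101 ± 28.3 to 1180 ± 219 (3.54 ± 0.24, adjusted p = 4.7e-07). S100g, the calcium-binding protein calbindin-D9k (mm9 chromosome X, 159399924 to 159402531), rose from 272 ± 119 to 3280 ± 1180 (3.6 ± 0.56, adjusted p = 0.0044). Slc25a20, the carnitine carrier of mitochondria, rose from 6720 ± 1060 to 11100 ± 329 (0.74 ± 0.1, adjusted p = 0.00026). Ncor1 itself fell from 3610 ± 125 to 1840 ± 96.1 (-0.97 ± 0.07, adjusted p = 2.6e-07).

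Of 23 genes of fatty acid oxidation and PPAR targets 13 rose and none fell, 15 adjusted over the list alone (camera adjusted p = 5.2e-19; adjusted p = 0.0097 with an estimated correlation). They include Cpt2 (0.57 ± 0.08), which releases acyl groups from carnitine in mitochondria, Ehhadh (0.53 ± 0.08) of the peroxisome and Acadl (0.57 ± 0.09). Of 16 LXR targets and lipogenesis genes 6 rose and 1, Nr1h3, fell, 10 and 1 adjusted over the list alone (camera adjusted p = 7.5e-12; adjusted p = 0.014 with an estimated correlation). The sterol exporters Abca1 (1.14 ± 0.12), Abcg5 (2.25 ± 0.29) and Abcg8 (1.52 ± 0.21) and the lysophospholipid acyltransferase Lpcat3 (0.63 ± 0.08) rose. Of 19 cholesterol synthesis genes none passed, and none adjusted over the list alone (camera adjusted p = 0.88). In the corepressor complex itself, Tbl1xr1 (1980 ± 89 to 3990 ± 303, adjusted p = 3.6e-07) and Tbl1x (1100 ± 70 to 1770 ± 172), its WD-repeat subunits, rose. These 2 and Ncor1 were the members of 6 that changed, also over the list alone (camera adjusted p = 0.061).

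Of 17 clock genes 3 rose, also over the list alone: Arntl (0.96 ± 0.16) and Npas2 (1.1 ± 0.18), which activate clock genes, and Bhlhe40 (camera adjusted p = 2.2e-05; adjusted p = 0.23 with an estimated correlation). Of 16 bile acid and xenobiotic receptor targets the exporters Abcb1a (0.61 ± 0.12) and Abcc2 (0.84 ± 0.17) rose and Abcc3 fell by 0.46 ± 0.09, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.18 with an estimated correlation). Of 18 absorptive colonocyte markers the monocarboxylate carrier Slc16a1 (0.61 ± 0.1) and the sodium channel subunit Scnn1b (0.86 ± 0.19) rose, 3 adjusted over the list alone (camera adjusted p = 5.7e-05; adjusted p = 0.23 with an estimated correlation). Of 21 junction genes Cldn8, a claudin of the distal colon, rose from 3130 ± 607 to 6720 ± 416 and Tjp3 rose, 3 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.53 with an estimated correlation). None of 18 oxidative phosphorylation genes passed, over all genes or over the list alone (camera adjusted p = 6.3e-06, upward; adjusted p = 0.23 with an estimated correlation).

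Of 12 tuft cell markers Hpgds, a prostaglandin D synthase, fell by 0.75 ± 0.12 and the taste channel Trpm5 by 0.57 ± 0.14, and 9 fell adjusted over the list alone (camera adjusted p = 5.8e-07; adjusted p = 0.23 with an estimated correlation). Of 18 antimicrobial and epithelial defence genes Itln1 (1400 ± 970 to 51.8 ± 16.1) and Pigr, the carrier of secreted immunoglobulin (-0.42 ± 0.09), fell and Sprr2a1 rose by 0.64 ± 0.13, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.24 with an estimated correlation). Of 13 neuron and glia markers Tubb3 fell by 0.47 ± 0.1, 1 adjusted over the list alone (camera adjusted p = 0.00049; adjusted p = 0.43 with an estimated correlation). No member of 28 cytokines (median -0.62), 15 T and NK cell markers (-0.62), 16 macrophage markers (-0.39), 19 antigen presentation genes (-0.55), 18 interferon genes (-0.37), 18 genes of the unfolded protein response (-0.32) or 11 smooth muscle markers (-0.22) passed over all genes. Camera placed each of these lists low (adjusted p of 0.0025, 0.0019, 0.017, 0.0064, 0.026, 0.0042 and 0.0015; adjusted p = 0.51, 0.55, 0.61, 0.74, 0.78, 0.56 and 0.53 with an estimated correlation). None of 14 neutrophil markers (median -0.18) or 14 B and plasma cell markers (-0.68) passed over all genes, and 1 neutrophil marker was higher adjusted over the list alone. Neither list was called (camera adjusted p = 0.44 and 0.05). Adjusted over the list alone 2 cytokines, 2 genes of the unfolded protein response and 4 smooth muscle markers fell. The largest falls named by the rule included Retnlb, a goblet cell product with antibacterial activity (21300 ± 15300 to 660 ± 418), Pla2g4c, a phospholipase (1840 ± 1690 to 70.3 ± 23.2), and Mptx1, a pentraxin (287000 ± 139000 to 42500 ± 14300), all with a wide spread in the F/F naive libraries. Adamts18 (2.62 ± 0.59) and G6pc2 (2.38 ± 0.55) were among the largest rises. None of the 9 acinar markers passed, over all genes or over the list alone (camera adjusted p = 0.0027, upward; adjusted p = 0.55 with an estimated correlation), with the library DIEC naive 1 far above all others.

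In all 408 genes changed, 258 higher and 150 lower. TMM rescaling shifted the log2 changes by a median over genes of 0.038 and gave 325 higher and 123 lower. The authors' deposited table has 330 higher and 317 lower, 329 of them called in the same direction here and 0 in the opposite. DESeq2 on recovered reads called 826 genes, and 271 and 232 were called by limma without F/F naive 2 and F/F naive 3. The calls of 7 named genes ended without a single library: Adamts18 (4 such libraries, adjusted p 0.057 to 0.091), G6pc2 (5, 0.072 to 0.12), Pigr (5, 0.051 to 0.082), Pla2g4c (7, 0.056 to 0.1), Scnn1b (6, 0.054 to 0.093), Trpm5 (6, 0.064 to 0.14) and Retnlb (without F/F naive 2, F/F naive 3 or DIEC naive 4, 0.052 to 0.061). A fit of the 2 groups alone called 600 genes, 291 higher and 309 lower, so the majority of higher genes did not hold there. In that fit Retnlb (adjusted p = 0.1), Itln1 (0.1), Pla2g4c (0.15), Mptx1 (0.073) and Adamts18 (0.085) were not called. With voom Itln1 (0.14) and Pla2g4c (0.19) were not called, and after TMM rescaling Pigr (0.056) was not.

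**Figure D3:**
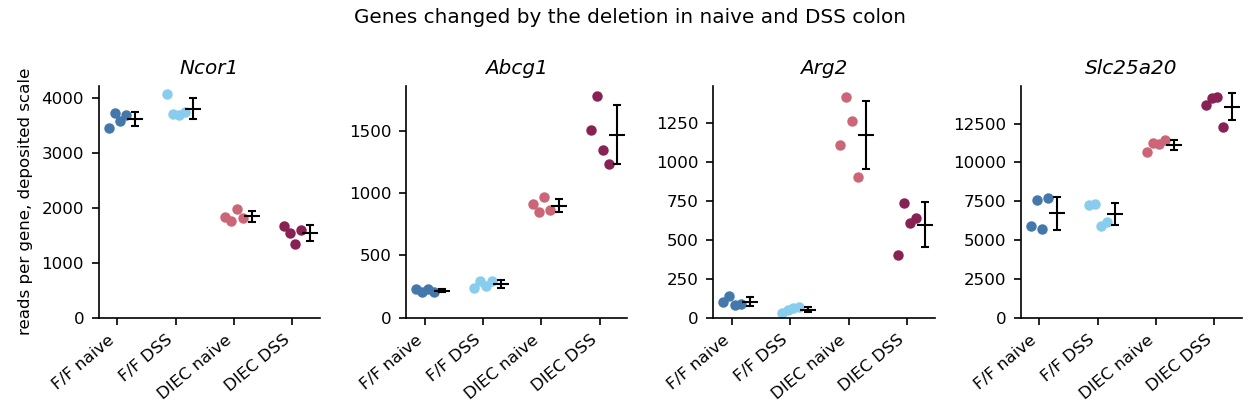
Reads per gene on the deposited scale (linear axes from 0) of Ncor1, Abcg1, Arg2 and Slc25a20 in the 4 groups, with 1 point per library and black marks for the mean ± SD (n = 4). Ncor1 falls with the deletion from 3610 to 1840 in naive colon and from 3800 to 1540 with DSS, and the other genes are higher in all DIEC libraries than in all F/F libraries.

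With DSS, the deletion raised 11 and lowered 1 of 23 genes of fatty acid oxidation and PPAR targets, and raised 7 and lowered 2 of 16 LXR targets and lipogenesis genes. It also raised 5 of 28 cytokines and chemokines and 6 of 18 absorptive colonocyte markers. Camera called these 4 lists, the first 2 also with an estimated correlation (adjusted p = 0.014, 0.022, 0.24 and 0.11 with an estimated correlation). Abcg1 was at 270 ± 29.5 in F/F and 1470 ± 238 in DIEC (SD, n = 4; log2 change 2.44 ± 0.11 SE, adjusted p = 6.7e-11), Arg2 at 51.9 ± 16.2 and 599 ± 142 (3.52 ± 0.24, adjusted p = 2.5e-07) and Slc25a20 at 6660 ± 717 and 13600 ± 891 (1.03 ± 0.1, adjusted p = 1.6e-06). Cxcl1 was at 16 ± 6.61 and 58.3 ± 13.2 (1.85 ± 0.26, adjusted p = 7.7e-05) and Tnf at 107 ± 10.6 and 190 ± 81 (0.74 ± 0.21, adjusted p = 0.013). Nxpe2 (mm9 chromosome 9, 48126087 to 48148981, minus strand) fell from 4450 ± 1490 to 180 ± 32.6 (-4.56 ± 0.33, adjusted p = 2.3e-06). Ncor1 fell from 3800 ± 184 to 1540 ± 139 (-1.31 ± 0.07, adjusted p = 1.3e-09), and Tbl1xr1 rose by 0.8 ± 0.08.

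Of 23 genes of fatty acid oxidation and PPAR targets 11 rose and 1, Fabp2, fell, 14 and 2 adjusted over the list alone and 14 and 0 after TMM rescaling (camera adjusted p = 2.1e-13; adjusted p = 0.014 with an estimated correlation), with Acadl up by 0.87 ± 0.09. Of 16 LXR targets and lipogenesis genes 7 rose and 2 fell (Nr1h3 and Acly), also over the list alone (camera adjusted p = 4.6e-10; adjusted p = 0.022 with an estimated correlation), with Abcg5 up by 2.53 ± 0.29 and Abca1 by 0.97 ± 0.12. Of 28 cytokines and chemokines 5 rose, also over the list alone (camera adjusted p = 5.8e-07; adjusted p = 0.24 with an estimated correlation): Cxcl1, Cxcl2 (3.7 ± 0.65), Cxcl3, Cxcl5 (2.03 ± 0.35) and Tnf. Of 14 neutrophil markers Ly6g (1.53 ± 0.21), S100a9 (2.4 ± 0.52) and S100a8 (1.73 ± 0.45) rose, also over the list alone (camera adjusted p = 0.00011; adjusted p = 0.25 with an estimated correlation), and the list was not called with voom (0.16). The mean log2 level of the cytokines, relative to all 16 libraries, was 0.35, 1.18, -0.25 and 0.63 in DIEC DSS 1 to 4. In F/F DSS 1 to 4 it was -0.04, 0.08, 0.25 and -0.08. The neutrophil markers were at 0.32, 0.83, -0.37 and -0.05 in DIEC DSS and at -0.21, -0.44, -0.06 and -0.4 in F/F DSS. DIEC DSS 2 was thus highest in both lists. Of 18 antimicrobial and epithelial defence genes 4 rose, among them Sprr2a1 (1.34 ± 0.13) and the serum amyloid Saa1 (0.79 ± 0.22), and 1, Pigr, fell, also over the list alone (camera adjusted p = 4.6e-05; adjusted p = 0.18 with an estimated correlation). The call of Saa1 ended without F/F DSS 1 (0.69, adjusted p = 0.051).

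Of 18 absorptive colonocyte markers 6 rose, also over the list alone, and 9 after TMM rescaling (camera adjusted p = 1.3e-07; adjusted p = 0.11 with an estimated correlation), such as Ceacam20 (0.7 ± 0.11) and the carbonic anhydrase Car4 (0.8 ± 0.16). Of 16 goblet cell markers 4 rose and 1, Creb3l1, fell, also over the list alone (camera adjusted p = 9.6e-05; adjusted p = 0.45 with an estimated correlation), with the trefoil peptide Tff3 up by 0.84 ± 0.22 and the mucus lectin Zg16 by 0.73 ± 0.14. Of 15 enteroendocrine markers Gcg, the glucagon precursor (1320 ± 89.6 to 2520 ± 248), Pyy (0.59 ± 0.1) and Neurod1 rose and Neurog3 fell, also over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.22 with an estimated correlation). Neurog3 had 26 reads in F/F and 3 in DIEC, a ratio of 7.8 (exact 95% interval 2.39 to 40.3). Of 18 crypt stem and Wnt target genes 9 fell, 10 adjusted over the list alone, while 5 fell and 1 rose after TMM rescaling (camera adjusted p = 0.12), with Axin2 down by 1.53 ± 0.27 and Znrf3, a Wnt receptor ligase, by 0.65 ± 0.1. Of 21 proliferation genes 16 fell, 19 adjusted over the list alone, while 3 fell after TMM rescaling (camera adjusted p = 0.00042; adjusted p = 0.56 with an estimated correlation). Tyms fell by 0.7 ± 0.13 and Mcm6 by 1.29 ± 0.3. Of 12 tuft cell markers 4 fell, also over the list alone, and 1 after TMM rescaling (camera adjusted p = 0.8), and Hpgds fell by 0.76 ± 0.12.

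Of 21 junction genes 5 rose and 3 fell, also over the list alone, or 12 and 2 after TMM rescaling (camera adjusted p = 3.4e-05, upward, with a median of 0.11 and a mean of 0; adjusted p = 0.28 with an estimated correlation). Cldn8 rose from 4010 ± 735 to 10500 ± 1560, and Cldn2 (1780 ± 1160 to 367 ± 78.1) and Cldn15 (1310 ± 524 to 414 ± 43.9) fell. Of 17 clock genes 5 rose, also over the list alone (camera adjusted p = 0.0035, upward, with a mean of 0.22 and a median of -0.21; adjusted p = 0.38 with an estimated correlation), with Arntl up by 1.27 ± 0.16, Npas2 by 1.37 ± 0.18 and Nfil3, a repressor of clock output, by 2.61 ± 0.41. The largest changes named by the rule also held Tex19.1 (3.36 ± 0.69), Clca4b (3.27 ± 0.59), the mucin glycosyltransferase A4gnt (54.5 ± 44.8 to 1.36 ± 1.49), the cytochrome Cyp2w1 (51.2 ± 27.6 to 1.69 ± 1.29), the thymus leukemia antigen H2-T3 (140 ± 84.2 to 19.8 ± 12) and the lectin Reg4 (4550 ± 2490 to 677 ± 211). None of 8 adipocyte markers (median 1.29) or 6 erythroid transcripts (1.12) passed over all genes or over the list alone, while camera placed both lists high (adjusted p of 0.00063 and 0.00048; adjusted p = 0.5 and 0.41 with an estimated correlation). The mean log2 level of the erythroid transcripts, relative to their mean over all 16 libraries, was 2.73 in DIEC DSS 2 and from -1.25 to -0.17 in the other 3 libraries of its group. Of 16 bile acid and xenobiotic receptor targets Abcc3, Aldh1a1 and Nr1i3 fell, also over the list alone, but 2 were higher and 0 lower after TMM rescaling, while the list lay high (median 0.1, camera adjusted p = 0.017; adjusted p = 0.24 with an estimated correlation).

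In all 5346 genes changed, 599 higher and 4747 lower. TMM rescaling shifted the log2 changes by a median over genes of 0.189 and gave 2568 genes, 1220 higher and 1348 lower, with 1947 called under both scalings, so that the count and the split of calls depend on the scaling. The authors' deposited table has 831 higher and 672 lower, 1240 of them called in the same direction here and 0 in the opposite. Log2 changes with the deletion in naive and in DSS colon, which share no libraries, correlated at a Pearson r of 0.33 and a Spearman rho of 0.31 across genes. Higher in both were 176 genes, where independent lists would share 8.5, and lower in both 108, where they would share 39, with 4 in opposite directions.

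The response to DSS itself differed between genotypes for 664 genes on the deposited scale, and for 117 after TMM rescaling. Cxcl1 changed with DSS by -0.11 in F/F and by 2.08 in DIEC, a difference of 2.19 ± 0.36 SE (n = 4 libraries per group, adjusted p = 0.0065). Tnf changed by 0.29 and 1.72, a difference of 1.44 ± 0.3 (adjusted p = 0.018). Krt36, a keratin (mm9 chromosome 11, 99963327 to 99966940, minus strand), changed by 0 and 3.11, from 27.2 ± 10.6 to 246 ± 105 in DIEC (difference 3.11 ± 0.47, adjusted p = 0.0057). Part of the Krt36 and Tnf differences was a lower naive level in DIEC. Krt36 was at 67.6 ± 11.5 in F/F naive (deletion in naive colon -1.34 ± 0.33, adjusted p = 0.043), and the deletion raised it by 1.77 ± 0.33 in DSS colon. Tnf was at 72.34 to 97.94 in the F/F naive libraries and at 42.58 to 60.96 in DIEC naive. Nxpe2 changed by -0.57 and -3.98 (difference -3.41 ± 0.46, adjusted p = 0.0063) and Cyp2w1 (mm9 chromosome 5, 139828571 to 139832987) by -0.29 and -3.89 (-3.6 ± 0.62, adjusted p = 0.0081). Neurog3 (mm9 chromosome 10, 61595838 to 61597511) differed by -2.45 ± 0.49 (adjusted p = 0.015).

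Of 28 cytokines and chemokines 4 had a higher log2 change with DSS in DIEC, Cxcl1, Tnf, Cxcl2 (4.36 ± 0.91) and Cxcl5 (2.34 ± 0.5), or 6 adjusted over the list alone (camera adjusted p = 4.3e-13; adjusted p = 0.11 with an estimated correlation). Of 18 antimicrobial and epithelial defence genes Pglyrp1 (0.49 ± 0.13) and Sprr2a1 (0.7 ± 0.18) had a higher log2 change in DIEC, 5 adjusted over the list alone (camera adjusted p = 3.7e-12; adjusted p = 0.014 with an estimated correlation). None of 14 neutrophil markers (median difference 0.71) or 15 T and NK cell markers (0.46) passed over all genes, or 1 and 0 adjusted over the list alone. Camera placed both lists high (adjusted p of 3e-06 and 0.00042; adjusted p = 0.22 and 0.53 with an estimated correlation). In DIEC DSS 1 to 4 the mean log2 level relative to all 16 libraries was 0.32, 0.83, -0.37 and -0.05 for the neutrophil markers. For the T and NK cell markers it was -0.71, 0.9, -1.3 and -0.16, so DIEC DSS 2 stood highest in both. Pglyrp1 changed by 0.01 in F/F and 0.5 in DIEC, and Sprr2a1 by -0.63 and 0.07. Of 15 enteroendocrine markers Gcg had a higher log2 change (-0.47 in F/F and 0.16 in DIEC, difference 0.62 ± 0.13) and Neurog3 a lower one, 3 and 1 adjusted over the list alone (camera adjusted p = 0.00017; adjusted p = 0.24 with an estimated correlation). Of 17 matrix genes Timp1, an inhibitor of metalloproteinases, had a higher log2 change (-0.91 in F/F and 0.3 in DIEC, difference 1.21 ± 0.28), 1 adjusted over the list alone (camera adjusted p = 8.4e-05; adjusted p = 0.41 with an estimated correlation). Of 21 junction genes Cldn2 had a lower log2 change (-2.18 ± 0.49), 2 adjusted over the list alone (camera adjusted p = 0.027, upward, with a median of 0.04 and a mean of -0.09; adjusted p = 0.55 with an estimated correlation). None of the 23 genes of fatty acid oxidation except Acaa2, which was lower, and none of the 16 LXR targets differed, over all genes or over the list alone (camera adjusted p = 0.49 and 0.19). Of the 21 proliferation genes, with a median difference of -0.83, none passed over all genes or over the list alone (camera adjusted p = 0.017; adjusted p = 0.76 with an estimated correlation). Clca4b (3.37 ± 0.84), the lipid transporter Mfsd2a (2.48 ± 0.63), A4gnt (-3.21 ± 0.72) and the tryptophan dioxygenase Tdo2 (-2.97 ± 0.74) were among the largest differences. Tdo2 had 152 reads in DIEC naive and 2 in DIEC DSS, a ratio of 81.9 (exact 95% interval 22.3 to 682). Ncor1 differed by -0.34 ± 0.1 (adjusted p = 0.064).

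**Figure D4:**
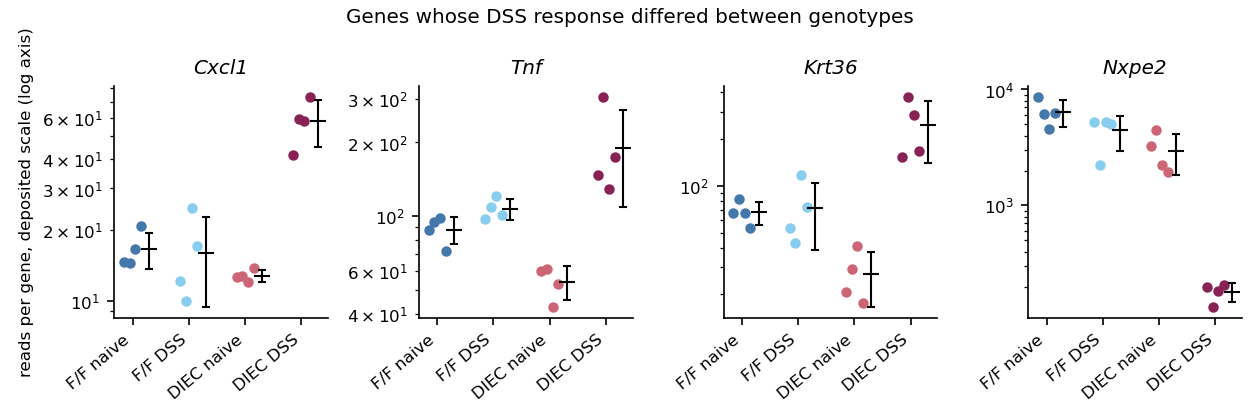
Reads per gene on the deposited scale (log axes) of Cxcl1, Tnf, Krt36 and Nxpe2 in the 4 groups, with 1 point per library and black marks for the mean ± SD (n = 4). With DSS, Cxcl1 is at 16 in F/F and 58.3 in DIEC, Tnf at 107 and 190, Krt36 at 71.8 and 246, and Nxpe2 at 4450 and 180.

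In all 664 genes differed in their response, with a log2 change higher in DIEC for 53 and lower for 611. TMM rescaling, which shifted the log2 differences by a median over genes of 0.152, gave 117 genes, 47 higher and 70 lower, of which 110 were called under both scalings. After it Clca4b (adjusted p = 0.087), Mfsd2a (0.076), A4gnt (0.069), Tdo2 (0.072) and Cldn2 (0.074) were not called. DESeq2 on recovered reads gave 510 genes, 232 higher and 278 lower. Without DIEC naive 1 and DIEC DSS 3 the limma count was 114, and with the replicate number as a block it was 1247, 110 higher and 1137 lower. Limma without trend gave 165 genes and ended the calls of 11 of the 17 named genes (adjusted p 0.051 to 0.077), namely Gcg (0.052) and the last 10 genes named in this paragraph. Cxcl2 was not called with a pseudocount of 0.1 (0.064). Leaving out 1 library gave 155 (without F/F naive 2), 158 (F/F naive 3), 205, 1661, 242 and 200 (F/F DSS 1, 2, 3 and 4), 144, 251 and 346 (DIEC naive 1, 3 and 4) and 200, 408 and 405 (DIEC DSS 2, 3 and 4). Of the named genes Cxcl1, Tnf, Krt36, Nxpe2, Cyp2w1, Neurog3 and Gcg kept their call without any single library. The calls ended without F/F naive 2, F/F naive 3 or F/F DSS 4 for Cxcl2 (adjusted p 0.051 to 0.055), without F/F naive 2, F/F DSS 4 or DIEC naive 3 for Cxcl5 (0.05 to 0.056), and without any of 7 to 13 libraries for A4gnt (7, 0.057 to 0.072), Timp1 (7, 0.051 to 0.069), Pglyrp1 (11, 0.055 to 0.084), Sprr2a1 (11, 0.055 to 0.089), Tdo2 (11, 0.056 to 0.081), Cldn2 (12, 0.05 to 0.083), Mfsd2a (12, 0.058 to 0.1) and Clca4b (13, 0.052 to 0.1).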

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

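The limma and list tests, the splits of the libraries with the draws of residuals, and the test of whether all 9 acinar genes moved together were planned before the results were seen. The tests of the 8 acinar genes without Clps, of a shared naive level, of the Per set and opposite clock genes, of epithelial genes and of TMM rescaling were chosen afterwards. In 318 sets of 4 libraries of 1 gene, 29 had a library far from the other 3, where chance gives about 1 in 20, or 15.9, and 7 of the 29 were in F/F DSS 2. Some sets hold only a few reads, for which that rate need not hold.

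In F/F DSS 2, interferon genes stood above the other F/F DSS libraries: Ifit3 at 1340 against 501 to 619, Irf7 at 12800 against 5610 to 6030, Rsad2 at 3010 against 806 to 1110 and Tap2 at 3810 against 2130 to 2290. Cdhr5 was at 33200 there (others 29000 to 29400), Nxpe2 at 2220 (5070 to 5270) and Cela2a at 0 (0.89 to 1.01). In DIEC DSS 2, Cdhr5 was at 38600 (31700 to 32400), Lypd8 at 927000 (679000 to 721000), Acadl at 12500 (11100 to 11200) and Reg4 at 363 (740 to 815). Other DSS libraries with a value apart were F/F DSS 1 for Ncor1 (4080 against 3690 to 3740), F/F DSS 3 for S100a9 (6.2 against 1.53 to 2.01) and Tdo2 (0 against 1.9 to 2.29), DIEC DSS 1 for Hpgds (324 against 285 to 290), DIEC DSS 3 for Neurog3 (0 against 0.88 to 1.04) and DIEC DSS 4 for Fabp2 (468 against 372 to 384). A read was worth 0.765 to 1.331, so the values of 0 for Cela2a, Tdo2 and Neurog3 differ from the others by few reads and do not set a library apart.

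Among naive libraries, DIEC naive 1 had Pnlip at 73200 (others 900 to 11900), Cela2a at 96400 (970 to 15200) and Tdo2 at 56.2 (34.6 to 36.4). DIEC naive 2 had Agr2 at 73100 (54100 to 55100), Pglyrp1 at 6590 (5760 to 5890) and Axin2 at 403 (514 to 530). DIEC naive 3 had Abcg5 at 768 (1370 to 1430) and Arntl at 1920 (1640 to 1680). F/F naive 3 had Myh11 at 45900 (31700 to 33900) and Smtn at 5850 (4070 to 4340), F/F naive 1 had Agr2 at 53800 (67700 to 68100), and F/F naive 4 had Tbl1x at 1210 (1060 to 1080).

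The response to DSS differed between genotypes in 17 named genes by the interaction test of limma, with these log2 differences. The log2 change was higher in DIEC for Cxcl2 (4.36), Clca4b (3.37), Krt36 (3.11), Mfsd2a (2.48), Cxcl5 (2.34), Cxcl1 (2.19), Tnf (1.44), Timp1 (1.21), Sprr2a1 (0.7), Gcg (0.62) and Pglyrp1 (0.49). It was lower for Cyp2w1 (-3.6), Nxpe2 (-3.41), A4gnt (-3.21), Tdo2 (-2.97), Neurog3 (-2.45) and Cldn2 (-2.18).

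Pancreatic acinar transcripts spanned 325-fold in read share over the naive libraries. A response of the colon itself to DSS needs naive libraries at a shared level, and their mean SD of the log2 share within a group was 2.7, where the largest of the 31 other lists had 0.51. Pancreas tissue carried into some naive samples needs the genes to move together: the median SD of a gene against the others was 1.38 (SD of the 9 values 0.52), which decides nothing, since Clps kept 329 to 445 reads in each DSS library, and was 0.2 over the 8 genes without Clps. The 4 naive libraries with 5 to 38 reads of the islet gene Ins2 were F/F naive 3 and 4 and DIEC naive 1 and 2, and the other 12 libraries had 0. Carried-over pancreas may thus account for the 8 genes and remains open for Clps, and no other biological explanation was tested.

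Of 17 clock genes 10 rose with DSS in each genotype (adjusted p = 0.28 and 0.25 with an estimated correlation). Another hour of collection needs genes of the opposite phase (Arntl, Npas2, Clock, Cry1 and Nfil3) to fall while Per genes rise. In F/F all 8 genes of the Per set rose (median 1.18), and of the 5 opposite ones 1 fell and 1 rose (median -0.15, SD 0.58). In DIEC 6 of 8 rose (0.67), and of the opposite ones 3 rose and 1 fell (0.57). The labels used here give no hour of collection, so another hour and a response to DSS cannot be told apart.

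All 21 proliferation genes fell with DSS in both genotypes (adjusted p = 0.38 and 0.41 with an estimated correlation). Less epithelium in the DSS libraries needs general epithelial genes to fall as much, and the median of 6 such genes was 0.17 (SD 0.27) in F/F and 0.3 (SD 0.24) in DIEC, against -1.87 and -2.79. The scaling of the libraries is argued against by the 21 of 21 genes that were lower in both genotypes after TMM rescaling. A lower share of dividing cells may therefore be biological, as a hypothesis found and tested on the same data, and cell loss and a halt of division were not told apart.

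For each pairwise comparison, 1 of 35 splits of its 8 libraries gave as many genes, the real split itself. In fits of the 2 groups alone, the real split called 8277 genes for DSS in F/F, 9049 for DSS in DIEC, 600 for the deletion in naive and 4041 for the deletion in DSS colon, and the highest of the other splits called 0, 0, 10 and 10. For the interaction, 1 of 100 draws of residuals, the real one, reached 664 genes, and the highest of the others gave 1. The other splits each mix the 2 real groups, so low counts were likely there in advance, and the real split cannot do better than 1 of 35. The draws likewise mix the residuals of all groups. These tests speak only against a random assignment of libraries to groups. They do not show how many called genes are real, and the interaction count depended on the scaling.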

How the results depend on the processing

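Counts of changed genes stayed within 1.5 times for DSS under all settings but a fold of at least 1.5, which by construction keeps fewer genes: 3447 (DSS in F/F), 5353 (DSS in DIEC), 217 (deletion, naive), 1542 (deletion, DSS) and 385 (interaction). For the deletion in naive colon DESeq2, which also called more unchanged genes in simulations, gave 826 against 408. For the deletion in DSS colon, 5346 genes became 2016 with quantile normalization, 2568 with TMM, 2705 with edgeR, 2686 with edgeR and RLE factors, 3071 with DESeq2 and 2499 with voom, settings that all rescale the libraries. For the interaction, 664 became 73 with quantile normalization, 117 with TMM, 135 with edgeR, 141 with RLE factors and 111 with voom. DESeq2, which also rescales, gave 510, with 232 higher and 278 lower. TMM moved the median of all genes from -0.164 to -0.017 and the lower calls from 611 to 70. The excess of lower genes thus depended on the scaling. The count was 165 without trend and 114 without DIEC naive 1 and DIEC DSS 3, and the cause of these drops was not tested.

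Leaving out 1 library gave 7279 to 7809 genes for DSS in F/F, 8886 to 9367 for DSS in DIEC, 232 to 386 for the deletion in naive colon, 4024 to 5846 in DSS colon and 144 to 1661 for the interaction. The correlation of DSS fold changes, 0.811, was 0.823 under the stricter filter and 0.784 to 0.812 without 1 library. Of the list tests, 84 calls became 5 with an estimated correlation, 51 with fry (38 in both, in the same direction) and 78 to 85 without 1 library.

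Whether replicate numbers pair the samples is unsettled: 8 of 24 same-numbered pairs correlated above 0.1 (-0.25 to 0.46), and 6 of 16 libraries correlated best with their own number. Pairs of replicates 1 to 4 were at 0.22, 0.03, 0.21 and 0.18 between F/F naive and DIEC naive. Between F/F DSS and DIEC DSS they were at 0.46, 0.29, -0.25 and 0.07. With the replicate number as a block every count was higher than in the main setting: 1247 for the interaction, and 8623, 9922, 513 and 5865 for the others. Among named genes, Ncor1 with DSS in DIEC turned from -0.26 to 0 with DESeq2 (adjusted p = 0.99), and Lypd8 from 0.63 to 0 with quantile normalization, which fixes the top-ranked gene by construction. Lypd8 lost its call there. Besides Lypd8, a call ended under some setting for 6 of 42 named genes with DSS in F/F, 3 of 40 with DSS in DIEC, 9 of 33 and 1 of 42 with the deletion in naive and DSS colon, and 11 of 17 in the interaction. The fold of at least 1.5 was not applied in these counts of named genes. Genes with few reads were limited by depth.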

Other observations

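The genes in the next paragraph were picked after their values were seen, with their tests taken from the planned limma model. The tests of the Per set and of the lists of receptor targets were chosen after the result was seen.

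Several further genes were higher or lower with the deletion. Sgk1, a kinase that sustains sodium uptake, went from 5880 ± 831 in F/F to 19000 ± 3420 in DIEC naive colon (SD, n = 4; log2 change 1.68 ± 0.14 SE, adjusted p = 2.6e-06) and was higher by 1.43 ± 0.14 with DSS. The epithelial calcium channel Trpv6 rose by 1.46 ± 0.29 and 1.78 ± 0.29, the phosphate transporter Slc34a2 by 1.56 ± 0.31 and 1.43 ± 0.31, and the zinc exporter Slc30a1 by 1.03 ± 0.17 and 0.91 ± 0.17. Mt1, a metallothionein, passed narrowly (2.02 ± 0.47, adjusted p = 0.045, and 1.39 ± 0.47, adjusted p = 0.042). The cytokine Il18 rose by 0.93 ± 0.11 and 0.96 ± 0.11, while the water channel Aqp4 fell from 22500 ± 2510 to 10500 ± 2400 in naive colon. Socs3, a feedback inhibitor of cytokine signalling, rose with DSS in DIEC from 272 ± 26.9 to 1120 ± 418, and its response differed from that in F/F by 1.68 ± 0.34 (adjusted p = 0.024).

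Arntl and Npas2 were higher with the deletion by a mean log2 change of 1.03 in naive colon. Another hour of collection for the DIEC libraries was taken to need the Per set to fall about as much. Its median over 8 genes was 0.17 (SE 0.06 across genes, not libraries), which argues against such a shift there. The labels give no hour, so a shift that leaves the Per set level stays open. In DSS colon their mean was 1.32 and the Per set moved in the direction this explanation needs, with a median of -0.33 (SE 0.05; -0.14 after TMM rescaling) and 0 of 8 genes lower past the threshold. That argues against such a shift as the whole cause, while a smaller or other shift in hour stays open.

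Because NCoR1 joins several nuclear receptors, lists of targets of 5 of them were tested as hypotheses in naive and in DSS colon. The test was limma's camera with an estimated correlation. It was repeated on the members outside the planned lists, the genes given by the naming rule and the genes picked above, called unseen below. These members come from the same 16 libraries and may move with the others, so they are no independent test. Each set of 10 tests was adjusted together. Genes induced by aldosterone may be released by the deletion: 4 of 10 were higher in naive and 7 of 10 in DSS colon (larger adjusted p = 0.0062), and the 7 unseen members gave an adjusted p = 0.018 in each. Of these 7, 2 passed over all genes in naive and 5 in DSS colon. Scnn1b of this list is also an absorptive colonocyte marker, and other causes of the rise were not tested. Vitamin D receptor targets, with 5 of 8 higher in each (larger adjusted p = 0.0016), stay open, since their 4 unseen members gave adjusted p = 0.28 and 0.48. Genes repressed by REV-ERB, with 2 and 4 of 10 higher (larger adjusted p = 0.0062), stay open too, as their 3 unseen members gave adjusted p = 1 and 0.67. For thyroid hormone receptor targets (0 of 8 higher in both, larger adjusted p = 0.39) and retinoic acid receptor targets (0 of 9 in both, 0.86) the values argue against a release. Hr and Thrb of the thyroid list were lower with the deletion in DSS colon, though not after TMM rescaling, under which 2 retinoic acid receptor targets were higher there.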
